A study of Mus musculus with 5 samples.

How the data were processed

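Poly-A enriched RNA of 5 mouse hearts, labelled as whole, had been sequenced, 3 from mice on a high-fat, high-sucrose diet and 2 from mice on chow, all given iron. The values used are raw counts per gene, 1 table per library, as deposited by the authors. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2 were used with the GRCm38 build. Per the file headers, each table lists Ensembl gene IDs, exon coordinates, strand, exon length and the count. The roles and options of the tools, the strand setting, the handling of reads that map to several places and the annotation release are not given in the sources used here. Reads of paralogs, processed pseudogenes, overlapping genes and antisense genes may therefore be shared between genes, and values of such genes are uncertain.

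Each table held 49315 genes. Symbols and coordinates came from the files and GENCODE M21 (GRCm38), in which 49056 of the genes were found, 91.4% of them with the same start and end. Total counts were 16546113, 14362766 and 15076251 in HFHS replicates 1, 2 and 3 and 17774735 and 17331356 in chow replicates 1 and 2. A count of 0 allows a level of up to 0.169 to 0.209 CPM (3 counts of the library), which covers counting error only. Pairs of libraries were compared by a chi-square of their counts; its value per degree of freedom was 2.89, 5.33 and 6.71 between HFHS libraries, 10.5 between the chow libraries and 58.7 to 77.1 between groups, so no pair differed by as little as sampling noise.

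Before the data were examined, the groups, tests, gene lists, marker lists, named genes and most alternatives were fixed. Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalization, glmQLFit and glmQLFTest on the diet group, Benjamini-Hochberg adjusted p of 0.05). Log2 fold changes are HFHS minus chow; standard errors are approximate, from the coefficient and the F statistic. CPM values use TMM-adjusted library sizes, except summed markers, which use the total counts. The named genes were the 12 that rose and the 12 that fell most among genes past the threshold, at a mean of at least 4 CPM in a group and with no overlap of the groups, leaving out predicted genes; the 4 members of each gene list with the smallest p; and a fixed set of iron, ferroptosis and heart stress genes. The text gives those of them that represent each list; 3 that met the rule are not reported here.

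The 21 gene lists and 19 marker lists were tested with camera (limma 3.58.1), a competitive test, with a preset inter-gene correlation of 0.01 and, beside it, an estimated one, where at least 5 members were tested. P-values were adjusted over the gene lists and over the marker lists separately. The gene lists were ferroptosis-promoting, ferroptosis-restraining, iron handling, NRF2 targets, fatty acid oxidation, lipid synthesis, glucose handling, nuclear and mitochondrial oxidative phosphorylation, cardiac stress, calcium handling, matrix, cytokines, interferon, antigen presentation, integrated stress, heat shock, p53 targets, clock, immediate early and proliferation genes. The marker lists were of cardiomyocytes, fibroblasts, endothelium, pericytes, macrophages, other blood cells, fat, mesothelium, nerve, skeletal muscle, lung, thymus and sex.

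Alternatives were other size factors, DESeq2 1.42.0, limma-voom, other filters on low counts, leaving out mitochondrially encoded genes, leaving out each library, the replicate number as a block, and other thresholds. Added after the data were seen were offsets per library from a smooth trend (mgcv 1.9.3) on exon length or median transcript length and on the GC content of the transcripts, which was known for 99.8% of tested genes. The fit was tested on simulated data for the comparison of 3 HFHS with 2 chow libraries over 13988 genes. It recovered 28% of genes changed 1.25 fold, 62% at 1.5 fold, 84% at 2 fold and 96% at 4 fold, and 12.3% of its calls were false. Only 50 genes were changed at each fold, while 5417 genes were called in the real libraries. Shares of false calls, here and with the added trend, depend on that number and are not error rates of the real calls. With a length trend added to the simulated libraries, 93.2% of calls were false without the offsets (13935 genes) and 8.5% with them (13900 genes). That trend was set on exon length, which the offsets also use, so its removal does not show that every length effect is removed in the real libraries. In simulated lists, camera called the shifted list, and 5 of the unshifted lists had an unadjusted p under 0.05 with the preset correlation. The simulated genes were drawn independently of each other, while the tested lists had estimated correlations as high as 0.80 (erythroid). The simulation therefore does not show that the p-values with the preset correlation hold for these lists.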

Results

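Messenger RNA was measured by poly-A RNA sequencing in 5 hearts, labelled as whole, of mice that had eaten either standard chow or a high-fat, high-sucrose (HFHS) diet for 18 weeks. Every mouse received a single intravenous dose of iron dextran, a complex of iron with a sugar polymer, and the hearts were perfused with saline and collected 48 hours later. There were 3 HFHS libraries and 2 chow libraries. The libraries held between 14362766 and 17774735 counts each, and between 19713 and 20278 genes had at least 1 count. Mitochondrially encoded genes took 30.3% to 33.8% of the counts. The comparison asks how the heart's gene expression differs between the diets once iron has been given; no library without iron is part of it, so no effect of iron itself was measured. Nothing beyond the labels says that the libraries came from separate mice, and p-values measure only the spread between these libraries.

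In hearts of HFHS mice 19 of 30 genes of fatty acid oxidation and 12 of 23 genes of calcium handling and ion channels rose, while 9 of 9 red blood cell markers, 11 of 13 macrophage markers and 12 of 16 antigen presentation genes fell. Of 14221 genes tested with edgeR's quasi-likelihood test, 5417 passed a Benjamini-Hochberg adjusted p of 0.05, of which 2756 were higher and 2661 lower in HFHS hearts. A change of at least 2 fold was fitted for 309 of the higher and 425 of the lower genes. The groups did not overlap in 58.6% of tested genes, where chance gives 20% for 3 libraries against 2. Fold changes also followed gene length, and the median log2 fold change went from -0.47 in the shortest of 10 equal bins of genes to 0.32 in the longest. With offsets for each library's trend on exon length and GC content, a step chosen after the data were seen, the rank correlation of fold change with exon length went from 0.43 to 0.037 and that with transcript length from 0.377 to 0.18, so part of the trend remained; 4369 genes passed, and 3523 of the 5417 calls were kept in the same direction.

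**Figure D1:**
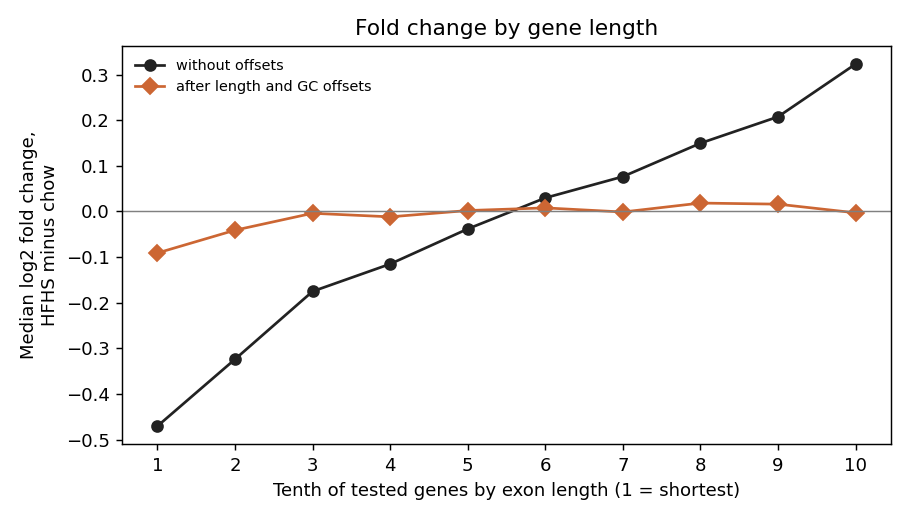
Median log2 fold change (HFHS minus chow, vertical axis) of the tested genes in 10 equal bins by exon length (horizontal axis, 1 is the shortest), without offsets and after length and GC offsets. The black points climb from -0.47 to 0.32, and the orange points stay between -0.09 and 0.02.

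Among the genes that rose most, Nt5c1a, a cytosolic nucleotidase that makes adenosine from AMP, went from 1.26 ± 0.132 CPM (SD, n = 2) in chow hearts to 10.6 ± 1.13 CPM (SD, n = 3) in HFHS hearts. Slc8a1 (ENSMUSG00000054640, chromosome 17 from 81388691 to 81649607, GRCm38), the sodium-calcium exchanger that removes calcium from heart muscle cells, rose 5.03-fold from 27.5 ± 3.42 CPM to 138.6 ± 4.67 CPM, with a log2 fold change of 2.33 (SE 0.093) and an edgeR adjusted p of 2.73e-09. Gpam (ENSMUSG00000024978, chromosome 19 from 55069734 to 55099451), the mitochondrial enzyme that starts triglyceride synthesis, rose 4.83-fold from 39.2 ± 1.96 CPM to 189.5 ± 5.78 CPM, with an adjusted p of 1.70e-09. Hipk2, a nuclear protein kinase, rose 6.52-fold, and Pdpr, the regulatory subunit of the phosphatase that activates pyruvate dehydrogenase, rose 4.91-fold. The cyclic nucleotide phosphodiesterase Pde11a rose 7.36-fold, the cyclic GMP-dependent kinase Prkg1 4.74-fold, the peptide hormone gene Edn3 4.33-fold, Pm20d2 4.26-fold and Lmbrd2 4.12-fold. Zbtb16, a glucocorticoid-induced transcription factor, rose 5.04-fold and was uneven within both groups. Its log2 fold change of 2.33 became 1.73 without chow replicate 1 and 3.38 without chow replicate 2. Leaving out chow replicate 1 also moved the log2 fold changes of Pde11a from 2.88 to 3.71 and of Pm20d2 from 2.09 to 2.68.

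The genes that fell most included red blood cell and macrophage genes. Hbb-bs (ENSMUSG00000052305, chromosome 7 from 103826534 to 103828096), an adult beta-globin gene, was at 1023 ± 104.8 CPM in chow hearts and 258.8 ± 88.5 CPM in HFHS hearts, with a log2 fold change of -1.98 (SE 0.182) and an adjusted p of 1.95e-06. Hba-a1 was 3.96-fold, Hba-a2 4.30-fold and Hbb-bt 4.78-fold lower; the copies of each globin gene are nearly identical, so the split of reads between them is uncertain. Alas2, the first enzyme of haem synthesis in red cell precursors, was 3.45-fold lower. Among macrophage genes, Aif1 was 4.77-fold lower, Fcer1g 3.52-fold, Wfdc17 5.44-fold and Fcna 5.71-fold. The metallothionein gene Mt2 was 3.81-fold lower and the matrix gene Spon2 4.32-fold lower. Without chow replicate 2 the log2 fold change of Fcna moved from -2.51 to -1.73 and that of Spon2 from -2.11 to -1.34, and both stayed past the threshold.

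Iron and ferroptosis genes changed in both directions. Ferroptosis, which the study set out to examine after intravenous iron, is a form of cell death driven by iron-dependent lipid peroxidation. Tfrc (ENSMUSG00000022797, chromosome 16 from 32608920 to 32632794), the transferrin receptor that brings iron into cells, rose 2.44-fold from 37.6 ± 2.73 CPM to 91.6 ± 25.7 CPM, with a log2 fold change of 1.28 (SE 0.166) and an adjusted p of 3.89e-05. Ncoa4, which delivers ferritin for breakdown, rose 1.67-fold, and Lpcat3, which puts polyunsaturated fatty acids into phospholipids, rose 1.47-fold. Both ferritin genes fell: the light chain Ftl1 (chromosome 7 from 45457944 to 45459884) from 295.4 ± 17.3 CPM to 121.0 ± 16.3 CPM, with an adjusted p of 2.67e-07, and the heavy chain Fth1 from 1252 ± 70.8 CPM to 798.1 ± 25.3 CPM, with an adjusted p of 5.67e-06. Gpx4 (ENSMUSG00000075706, chromosome 10 from 80047166 to 80056439), the peroxidase that repairs oxidised phospholipids and restrains ferroptosis, fell from 528.1 ± 29.4 CPM to 291.8 ± 29.8 CPM, with a log2 fold change of -0.86 (SE 0.0835) and an adjusted p of 3.42e-06. Sat1, a polyamine-degrading enzyme, was 2.05-fold lower. Ftl1, Gpx4 and Fth1 have exon lengths of 1340, 1724 and 866 bases. After the length and GC offsets the log2 fold change of Ftl1 was -0.94, of Gpx4 -0.57 and of Fth1 -0.24, all still past the threshold, while Cisd1, a mitochondrial iron-sulfur protein, moved from -0.42 to -0.03 and lost its call. Ferritin genes have processed pseudogenes that can share reads with them, so their values carry that uncertainty. Erythroid and macrophage markers fell in the same hearts, with median log2 fold changes of -1.99 and -0.75.

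Other markers of ferroptosis did not pass. Acsl4, which makes the oxidisable lipids, was at 14.8 ± 0.510 CPM in HFHS hearts and 15.3 ± 0.277 CPM in chow hearts, with an adjusted p of 0.767. Ptgs2, the prostaglandin synthase used as a ferroptosis marker, was at 0.803 ± 0.548 CPM and 0.576 ± 0.0283 CPM, with an adjusted p of 0.562. Chac1 was at 1.65 ± 0.357 CPM and 1.98 ± 0.501 CPM, with an adjusted p of 0.553. The haem oxygenase gene Hmox1 was at 5.56 ± 1.09 CPM and 7.65 ± 0.365 CPM, with an adjusted p of 0.0657, and passed without HFHS replicate 3, with 0.0348 (range over the alternatives 0.0192 to 0.505). The iron exporter Slc40a1 was at 29.2 ± 5.05 CPM and 30.9 ± 9.40 CPM, with an adjusted p of 0.744. The cystine transporter gene Slc7a11 had 0 to 2 counts and the hepcidin gene Hamp 0 to 4 counts per library, too few to test.

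**Figure D2:**
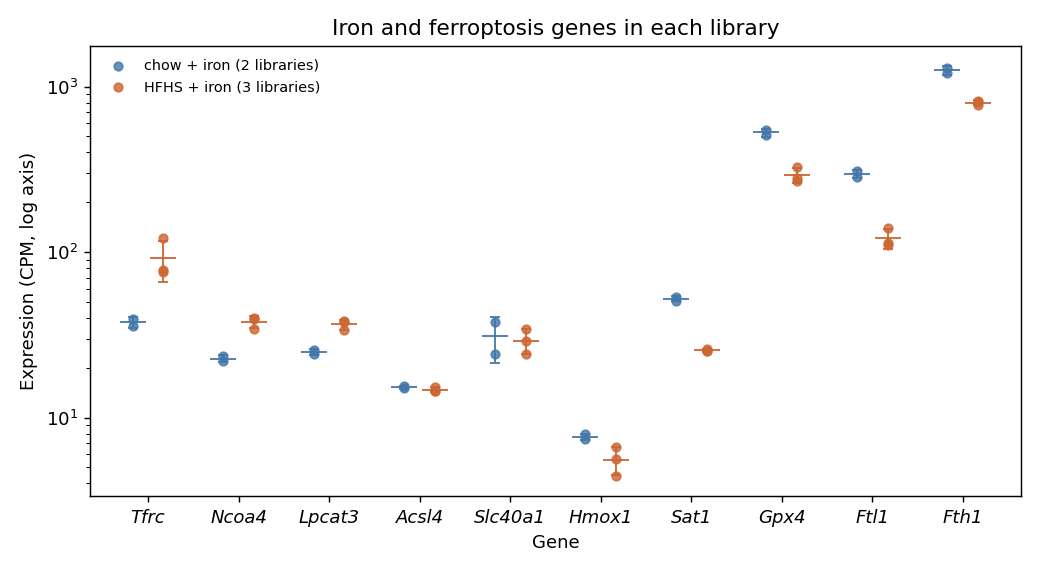
Expression of 10 iron and ferroptosis genes in CPM on a log axis. Each point is a library, blue for the 2 chow hearts and orange for the 3 HFHS hearts, with horizontal bars at the group means and error bars of 1 SD. Tfrc lies higher in all 3 HFHS libraries than in both chow libraries, Gpx4, Ftl1 and Fth1 lie lower, and Acsl4 and Slc40a1 do not separate in this way.

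As groups, the lists fixed for these genes did not stand apart from the other genes. Of 24 tested members of the ferroptosis-promoting list, 6 rose, 2 fell and 16 did not pass, and 5 rose and 2 fell when adjusted over the list alone; the list's median log2 fold change was -0.01, its mean 0.07, and its camera adjusted p was 0.773. Of 26 ferroptosis-restraining genes, 2 rose, 6 fell and 18 did not pass, the same counts as when adjusted over the list alone, with a camera adjusted p of 0.133; without chow replicate 1 it passed with 0.0122, but not with an estimated correlation (adjusted p = 0.321; range of the first p over the alternatives 0.0122 to 0.517). Of 29 iron-handling genes, 7 rose and 9 fell, or 7 and 10 adjusted over the list alone, with a camera adjusted p of 0.449. Of 21 targets of the antioxidant regulator NRF2, 4 rose and 7 fell, or 4 and 8 adjusted over the list alone, with a camera adjusted p of 0.481; after the length and GC offsets 6 rose and 3 fell, and the median log2 fold change went from -0.18 to 0.002. Catalase (Cat) rose 1.52-fold and malic enzyme (Me1) 1.39-fold, while the peroxiredoxin gene Prdx1 was 1.58-fold lower.

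Of 30 genes of fatty acid oxidation and targets of the nuclear receptor PPAR-alpha, 19 rose, 1 fell and 10 did not pass, or 19 and 2 adjusted over the list alone, and the list was higher with a camera adjusted p of 8.01e-09, but not with an estimated correlation (adjusted p = 0.363). The receptor gene Ppara rose 3.82-fold from 8.36 ± 0.0417 CPM to 31.9 ± 4.31 CPM. The acyl-CoA synthetase gene Acsl1 rose 2.10-fold and the trifunctional protein gene Hadha 1.84-fold. Of 25 glucose-handling genes, 9 rose and 5 fell, or 10 and 5 adjusted over the list alone, with a camera adjusted p of 0.151; hexokinase Hk2 rose 1.58-fold, glycogen synthase Gys1 1.73-fold and glycogen phosphorylase Pygm 1.36-fold. Without chow replicate 2 this list passed with 0.0383, and with the transcript length and GC offsets with 0.00121, but not with an estimated correlation (adjusted p = 0.605 and 0.493; highest of the first p over the alternatives 0.448). Of 22 lipid and sterol synthesis genes, 4 rose and 2 fell, or 3 and 2 adjusted over the list alone, with a camera adjusted p of 0.746. Acacb, which makes the malonyl-CoA that holds back mitochondrial fatty acid entry, rose 1.94-fold, and the lipogenic gene Thrsp was 2.11-fold lower.

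Of 37 nuclear-encoded genes of oxidative phosphorylation, 27 fell and 2 rose, the same counts as when adjusted over the list alone, and the list was lower with a camera adjusted p of 3.92e-13, but not with an estimated correlation (adjusted p = 0.363). Ndufa4 was 2.03-fold, Cox7b 1.93-fold, Uqcrh 1.90-fold and Cox6c 1.88-fold lower. The median exon length of the list was 2101 bases, and its median log2 fold change of -0.43 was -0.16 after the length and GC offsets, with 18 lower and 4 higher. Of 13 mitochondrially encoded genes, 5 rose and none fell, also when adjusted over the list alone, with a camera adjusted p of 0.0154 and an adjusted p of 0.617 with an estimated correlation. After the length and GC offsets 12 of them rose and the median log2 fold change went from 0.13 to 0.50. The camera adjusted p was then 8.35e-12, but 0.362 with an estimated correlation. The offsets follow a trend over all tested genes and raise the fold changes of short genes. This list's median exon length was 784 bases, so the larger count rests on the offsets and does not make the rise firmer. The respiratory complex I gene mt-Nd5 rose 2.24-fold and mt-Nd4l 1.99-fold. However, mt-Nd4l had only 268 to 518 counts per library, against 388826 to 497114 for mt-Nd4 of the same list. Counts were also low for mt-Nd3 (1220 to 1991), mt-Co2 (486 to 626), mt-Co3 (677 to 946), mt-Atp6 (517 to 653) and mt-Atp8 (85 to 143). By contrast, mt-Co1 had 1808186 to 2257128. How reads that map to several places were handled is not given. The values of all these low-count genes are therefore uncertain, and so are the list's median, its counts of changed genes and its camera p-values.

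Of 16 tested genes of cardiac stress and hypertrophy, 7 rose, 1 fell and 8 did not pass, or 9 and 1 adjusted over the list alone, with a camera adjusted p of 0.000767 and of 0.363 with an estimated correlation. Myh7, the slow myosin heavy chain that adult mouse ventricles express at a low level, rose 3.08-fold from 198.8 ± 12.1 CPM to 613.3 ± 139.6 CPM. Nrap and Xirp2, proteins of the intercalated disc and muscle attachment sites, rose 2.21-fold and 1.81-fold. The natriuretic peptide genes, which heart muscle releases when stretched, did not pass. Nppa was at 38.9 ± 6.74 CPM in HFHS and 59.7 ± 39.4 CPM in chow hearts, and Nppb at 99.8 ± 23.3 CPM and 138.5 ± 99.6 CPM. Their chow libraries were far apart: the log2 fold change of Nppa was 0.29 without chow replicate 1 and -1.17 without chow replicate 2, and that of Nppb was 0.55 and -1.07, with adjusted p of 0.155 and 1.67e-06 for Nppa and of 0.0167 and 1.92e-05 for Nppb (ranges over the alternatives 5.86e-10 to 0.619 and 7.37e-08 to 0.949). Of 23 genes of calcium handling and cardiac ion channels, 12 rose, 3 fell and 8 did not pass, or 13 and 3 adjusted over the list alone, with a camera adjusted p of 1.77e-05 and of 0.588 with an estimated correlation. The L-type calcium channel gene Cacna1c rose 1.96-fold and the ATP-sensitive potassium channel gene Kcnj11 1.55-fold.

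Of 32 genes of the extracellular matrix and fibrosis, 18 fell, 2 rose and 12 did not pass, or 18 and 3 adjusted over the list alone, with a camera adjusted p of 0.0154 and of 0.595 with an estimated correlation. The collagen-binding gene Sparc was 1.60-fold, the elastin crosslinker Loxl1 1.67-fold and Postn 1.42-fold lower. Of 16 antigen presentation genes, 12 fell and none rose, or 14 and none adjusted over the list alone, with a camera adjusted p of 1.65e-10 and of 0.363 with an estimated correlation. The class II genes H2-Aa and Cd74 were 2.52-fold and 2.03-fold lower and the class I light chain B2m 2.18-fold lower. Fibroblast, endothelial and macrophage markers fell in the same hearts, with median log2 fold changes of -0.53, -0.43 and -0.75. Of 20 tested cytokine, chemokine and adhesion genes, 6 fell, none rose and 14 did not pass, also when adjusted over the list alone, with a camera adjusted p of 0.0899. Il1b went from 1.79 ± 1.08 CPM to 0.224 ± 0.0422 CPM. Its HFHS values of 0.187, 0.215 and 0.270 CPM lie near the level of 3 counts, 0.181 to 0.209 CPM in these libraries, so its fold is uncertain. The log2 fold change of Il1b moved from -2.96 to -2.16 without chow replicate 2, where the list passed with 0.0301, but not with an estimated correlation (adjusted p = 0.503; range of the first p over the alternatives 0.0301 to 0.406). Cxcl9 was 1.85-fold lower with an adjusted p of 0.00612, which was 0.117 without chow replicate 1 (range over the alternatives 2.27e-07 to 0.117). Of 22 type I interferon genes, 4 fell, or 3 adjusted over the list alone, and none rose, with a camera adjusted p of 0.0899. This list passed without HFHS replicate 1, with 0.00839, and without chow replicate 2, with 0.0301, but in neither case with an estimated correlation (adjusted p = 0.565 and 0.647), and its first p reached 0.391 at most over the alternatives. Bst2 was 2.24-fold and Irf9 1.44-fold lower.

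Of 25 genes of heat shock and the unfolded protein response, 9 fell, 2 rose and 14 did not pass, or 10 and 2 adjusted over the list alone, with a camera adjusted p of 0.0154 and of 0.729 with an estimated correlation. The secreted chaperone gene Manf was 2.09-fold lower and Xbp1, a transcription factor of the endoplasmic reticulum stress response, 1.67-fold lower, while the muscle chaperone Hspb7 rose 1.56-fold. The list's call was lost without chow replicate 2, with an adjusted p of 0.408, and after the length and GC offsets, with 0.194 (range over the alternatives 5.30e-07 to 0.408). Of 18 integrated stress response genes, 1 rose and 4 fell, or 1 and 3 adjusted over the list alone, with a camera adjusted p of 0.449; Nupr1 was 2.28-fold and Atf4 1.42-fold lower. Of 20 p53 target and apoptosis genes, 2 rose and 7 fell, also when adjusted over the list alone, with a camera adjusted p of 0.0714, which was 0.0417 without chow replicate 1, but 0.332 there with an estimated correlation (range of the first p over the alternatives 0.00812 to 0.0934). The cell cycle inhibitor Cdkn1a was 2.88-fold and the cell death gene Bax 1.69-fold lower. Of 18 circadian clock genes, 11 rose and 1 fell, also when adjusted over the list alone, with a camera adjusted p of 0.00573 and of 0.363 with an estimated correlation. Arntl, the activating arm of the clock, was 2.74-fold lower, while the clock output gene Tef rose 1.79-fold and the repressor Cry2 1.66-fold. Of 20 immediate early genes, 1 rose and 6 fell, also when adjusted over the list alone, with a camera adjusted p of 0.115. This list passed without HFHS replicate 2, with 0.00723, without HFHS replicate 3, with 0.0212, and without chow replicate 2, with 0.0404, but in none of these with an estimated correlation (adjusted p = 0.770, 0.706 and 0.647; range of the first p over the alternatives 0.00575 to 0.511). Klf4 was 1.69-fold and Klf2 1.80-fold lower, and Klf2 lost its call with DESeq2 (adjusted p = 0.0735, range over the alternatives 1.79e-15 to 0.0735). Of 22 proliferation genes, 4 fell, or 1 adjusted over the list alone, and none rose, with a camera adjusted p of 0.293. Pcna was 1.31-fold lower, and its log2 fold change of -0.39 became -0.17 and lost its call after the length and GC offsets (adjusted p = 0.177, range over the alternatives 0.00155 to 0.177). Cdk1 was 2.37-fold lower, with an adjusted p of 0.0269 that became 0.0906 without HFHS replicate 2, 0.0547 without HFHS replicate 3 and 0.403 without chow replicate 1, and 0.0885 with DESeq2 (range over the alternatives 0.00584 to 0.403).

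**Figure D3:**
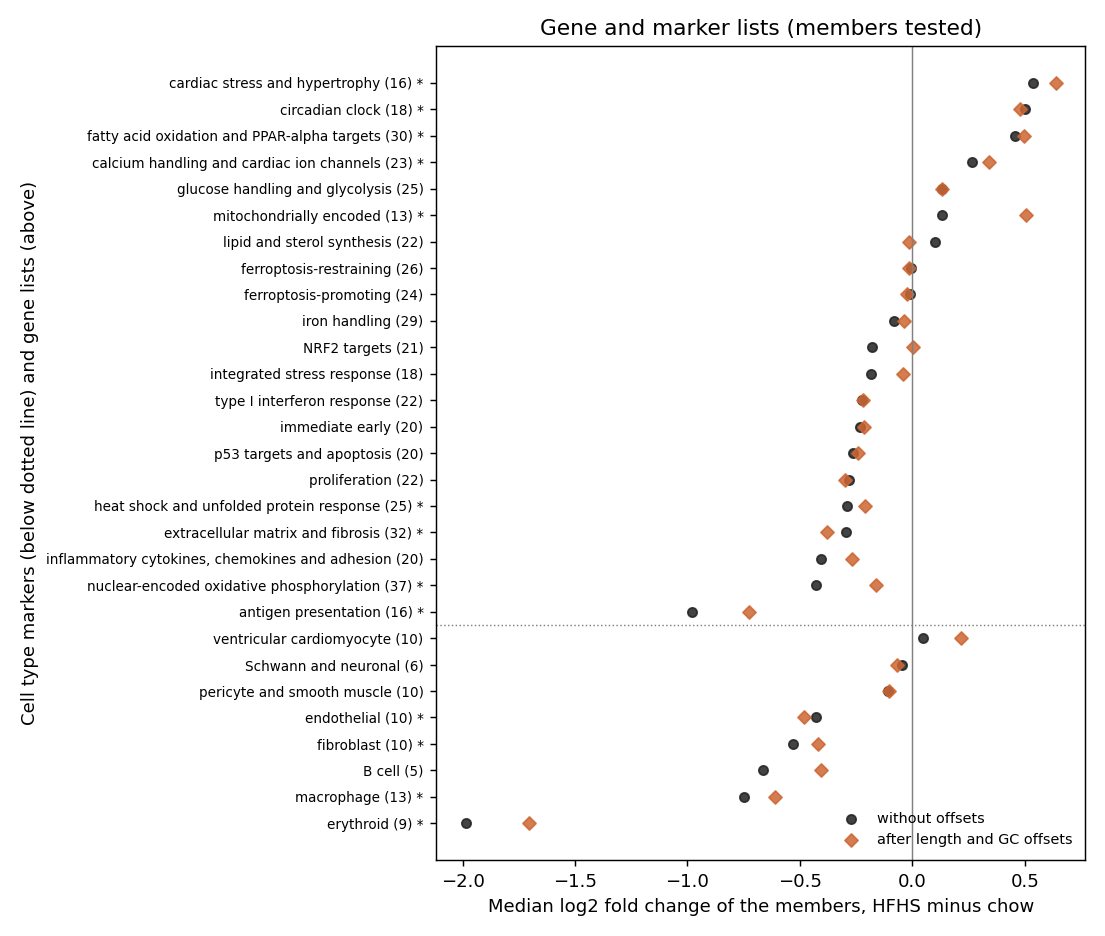
Median log2 fold change (HFHS minus chow) of the members of each list with at least 5 tested genes, without offsets and after length and GC offsets, with the number of members tested in brackets and an asterisk where the camera adjusted p was under 0.05. The mesothelial list, at 5.11 as fitted, is left off the axis. Erythroid markers lie lowest, at -1.99, and cardiac stress genes lie highest of the lists shown, at 0.54. Without chow replicate 2 the cardiac stress median was 0.21, below that of fatty acid oxidation at 0.49, and without chow replicate 1 it was 0.79.

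Markers of several cell types differed between the groups. All 9 erythroid markers fell, with a median log2 fold change of -1.99 and a camera adjusted p of 2.19e-10, and the summed erythroid markers were at 1751 and 1532 CPM in the chow libraries against 270.0, 370.6 and 550.4 CPM in the HFHS libraries. Of 13 macrophage markers 11 fell, with a camera adjusted p of 5.01e-07. Of 10 fibroblast markers 9 fell, with 1.46e-05, and of 10 endothelial markers 7 fell and 1 rose, with 0.000219. Of 5 tested mesothelial and epicardial markers 4 rose, with a camera adjusted p of 0.00374. The list's mean log2 fold change of 4.45 was 3.61 without chow replicate 1 and 5.50 without chow replicate 2. These means rest on genes with 0 counts in chow libraries, so they are not exact. The summed markers were at 12.9, 11.1 and 14.7 CPM in HFHS libraries and at 7.26 and 9.52 CPM in chow libraries. Without HFHS replicate 1 or 3, or with the stricter filter, the list had too few tested members for camera. None of the 5 lists passed with an estimated correlation, where the adjusted p = 0.0843 for the fibroblast, endothelial and macrophage lists, 0.142 for the mesothelial list and 0.150 for the erythroid list. These counts were the same when adjusted over the list alone. Ventricular cardiomyocyte markers went both ways, with 4 that rose and 4 that fell of 10, or 5 and 4 adjusted over the list alone, and a camera adjusted p of 0.438; with the transcript length and GC offsets the list passed as higher, with 0.0270, but not with an estimated correlation (adjusted p = 0.174, range of the first p over the alternatives 0.0270 to 0.719). Of 10 pericyte and smooth muscle markers, 1 rose and 3 fell, or 3 and 4 adjusted over the list alone, with 0.716. Of 5 B cell markers 2 fell, or 3 adjusted over the list alone, with 0.438, and none of 6 Schwann and neuronal markers passed, with 0.924.

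Other marker lists had fewer than 5 tested members. The summed white adipocyte markers were at 463.2 to 465.2 CPM in HFHS libraries and at 1198 and 1029 CPM in chow libraries, and nearly all of these counts came from Fabp4, which capillary endothelium also expresses; the fat cell gene Adipoq had at most 1 count in any library. The brown adipocyte sum was at 420.8 to 503.2 CPM against 870.7 and 937.3 CPM, while the brown fat gene Ucp1 had at most 2 counts; Fabp4, Adipoq and Ucp1 were singled out after their values were seen. The atrial sum was at 46.5 to 61.8 CPM against 110.1 and 59.2 CPM. Neutrophil markers summed to 2.30 to 4.25 CPM against 4.28 and 6.17 CPM, and T and NK cell markers to 2.65 to 3.69 CPM against 4.73 and 4.85 CPM. Skeletal muscle markers summed to 2.19 to 3.20 CPM against 2.81 and 3.63 CPM, and thymus markers to 2.19 to 3.02 CPM against 3.77 and 2.25 CPM. Lung markers had at most 8 counts and X-inactivation transcripts at most 12 counts in any library, and Y-linked markers were at 187.5 to 196.1 CPM against 168.3 and 146.7 CPM.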

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

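The offsets for length and GC content were chosen after the data were seen. The count of 5417 changed genes stayed within 1.5 times under every alternative except the added fold threshold: it was 4248 to 4929 with a library left out, where a lone chow library is assumed to vary like the HFHS group, 4236 with DESeq2, 5407 with limma-voom, 5402 to 5450 with other size factors, 5331 to 5565 with other filters and 6516 at an adjusted p of 0.1. With the threshold of at least 2 fold added it was 734, of which 309 were higher and 425 lower, since fewer genes meet both conditions. With the estimated correlation, 0 gene lists and 0 marker lists passed in the fit of the report, against 9 and 5 with the preset one. Of the alternatives only the fit without a filter gave any, the fibroblast, endothelial and macrophage lists, each with an adjusted p of 0.0449. The unshifted simulated lists, of genes drawn independently, also gave 0 at an unadjusted p under 0.05, fewer than the nominal rate. Without a filter on low counts, edgeR gave every gene the spread of the trend in place of its own (infinite prior degrees of freedom, against a median of 10.9), so that fit's small p-values for uneven genes such as Nppa, Nppb and Klf2 rest on that. With the preset correlation, 13 gene lists and 5 marker lists passed without a filter, and 8 to 12 gene lists and 4 to 6 marker lists under the other alternatives. Beyond the changes of call given in the report, the cytokine, interferon, p53 and immediate early lists passed without a filter, the p53 and immediate early lists with the replicate block, and the interferon and p53 lists with the transcript length offsets, where the heat shock list did not; none of these calls held with the estimated correlation. Replicate numbers share only a number: same-numbered libraries deviated with correlations of 0.003 and -0.06, and the replicate block gave 5332 genes, 11 gene lists and 5 marker lists.

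Of 76 genes named in the text with a call, 71 kept their call and direction in every alternative that gave a value, and none reversed. Cisd1, Cxcl9, Klf2, Pcna and Cdk1 lost theirs in at least 1. Genes that met the naming rule but are not named in the report above were left out of this count. Among those, Acaca, Taldo1, Nfkbia and Isg15 lost their call after the length and GC offsets (edgeR adjusted p of 0.327, 0.0862, 0.0657 and 0.340). Values that changed sign belonged to genes and lists without a call, and the cause was not tested. The log2 fold change of Slc40a1 ranged from -0.36 to 0.27 with a library left out, and was 0.065 with the replicate block and 0.21 with transcript length offsets. That of Chac1 ranged from -0.51 to 0.012, and was 0.030 with the length and GC offsets. Nppa ranged from -1.17 to 0.29 and Nppb from -1.07 to 0.55. The mean log2 fold change of the list B cell ranged from -0.89 to 0.68 and that of the list Schwann and neuronal from -0.23 to 0.059 with a library left out. The camera direction of the list NRF2 targets turned with the length and GC offsets, where its mean was -0.011, and that of the list lipid and sterol synthesis turned with both offsets, where its mean was -0.046 and -0.0057. The depth limits genes near the floor, such as Ptgs2, Slc7a11, Hamp and, in HFHS libraries, Il1b.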

Other observations

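The tests of explanations given here, the offsets and the ribosomal and nuclear RNA lists and the mesothelial, atrial and nuclear genes singled out were chosen after the results were seen. All 81 ribosomal protein genes, matched by symbol, fell in HFHS hearts, with a median log2 fold change of -1.07, and between -1.06 and -1.11 under the other size factors; their pseudogenes can share reads. Of 8 mesothelial markers, which mark the outer lining of the heart, 5 were tested and 4 of these rose in HFHS hearts, on few counts, while Wt1 did not pass; Upk3b had 24 to 46 counts in HFHS libraries and 0 and 10 in chow libraries. Msln had 23, 21 and 23 counts in HFHS libraries and 0 in both chow libraries, at least 17.1-fold higher against a floor of 3 counts over the group, and Lrrn4 was at least 10.4-fold higher. The list's median log2 fold change was 5.11 as fitted and 3.38 with both genes at these bounds. Of the atrial markers, Myl7 had 0 to 7 counts, Sln 0 to 1, Myl4 11 to 36, Stard10 198 to 411 and Nppa 484 to 1617 counts per library; the low counts of Myl7 and Sln go against the label of whole hearts, and whether atria were present is open.

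Long genes were higher and short genes lower in HFHS hearts, with a rank correlation of 0.43 across genes between fold change and exon length; genes are not independent replicates. After the offsets 3523 of 5417 calls were kept in the same direction. However, fold change still followed transcript length then, with a rank correlation of 0.18. The kept calls therefore cannot decide whether a length and GC trend of the libraries is the whole cause of the calls, and this stays open. The ribosomal protein fall was larger than that of other genes of like exon length and expression. Its median after the offsets was -0.82, against -0.10 to 0.08 for the middle of 10000 random lists matched on both. With the transcript length and GC offsets the median was -0.83. The matching used exon length, not transcript length, and the random genes were drawn independently, so a length effect is not excluded. More nuclear RNA in the HFHS libraries stays open. The median of 7 nuclear-retained RNAs was 0.55 after the offsets, against -0.37 to 0.38 for the middle of 10000 matched random lists, of which 20 were as high. Only 3 of the 7 RNAs were then called higher, and Neat1 was at -0.03. Without the offsets the median was 0.74, against -0.11 to 0.65 for such lists, with 5 called higher and Neat1 at 0.43. Offsets that take out the length trend may also take out part of such an effect. RNA integrity is not given in the sources used here and a difference between the groups cannot be separated from diet, which itself stays open as untested.

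Of 72 tested ferroptosis and iron genes 27 changed, where 38.1% of all tested genes did. After the offsets 16 of the 27 were kept in the same direction, where 65.0% of all calls were. Neither count therefore sets these genes apart from the others. Because the offsets left part of the length trend, the 16 kept calls do not show that it is not the whole cause of the 27 changes. It may account for the 11 that were not kept. Whether fewer macrophages in the HFHS hearts are the whole cause of the lower ferritin genes cannot be told apart from a change within cells, because Ftl1, at -0.94 after the offsets, lay below the median of the 13 tested macrophage markers, at -0.61, but 4 of the 13 lay as low, 1 of them level with it. A change in iron handling with diet stays open as an untested hypothesis.

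Macrophage and blood markers were lower in HFHS hearts. An even dilution of all other cell types by cardiomyocytes would lower them alike, but macrophage markers lay 0.48 below pericyte and smooth muscle markers on the log2 scale after the offsets, without Des and Abcc9, which cardiomyocytes also express (exact permutation of list members, two-sided, Holm adjusted p = 0.0145; genes are not independent replicates); against fibroblast and endothelial markers they lay 0.22 and 0.26 lower, with p = 0.155 for both, so a fall shared by these 3 cell types stays open. Of the tissue-resident macrophage markers, 7 of 7 were lower after the offsets. All 7 belong to the macrophage list itself and were picked after its fall was seen, so they are no separate test. Whether blood left in the chow hearts is the whole cause of the lower macrophage markers therefore stays open. For erythroid markers, blood left in the chow hearts cannot be told apart from other causes: 2 of 3 summed white blood cell lists were lower in every HFHS library, on few counts. A difference in resident macrophages between the diets is a hypothesis.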
